A study of Oryza sativa Indica Group and Oryza sativa Japonica Group with 12 samples.

How the data were processed

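H3K27me3 ChIA-PET was analysed in 12 rice samples in 6 groups, each with 2 labelled replicates. ChIA-PET enriches chromatin that carries a mark, here the histone mark H3K27me3, joins DNA ends held close together by proximity ligation, and reads both ends of each ligation product as a paired-end tag (PET). The groups were seedlings and roots of Minghui 63 (MH63), seedlings and roots of Zhenshan 97 (ZS97), Dongjin seedlings, and osemf2b seedlings in the Dongjin background. Per the labels' protocols, tissue was cross-linked with formaldehyde (1%, 10 min) and with the longer cross-linker EGS (1.5 mM, 30 min), chromatin was ligated through a biotinylated bridge linker, libraries were made with Tn5 transposase, and 150 bp paired ends were sequenced on an Illumina HiSeq X-Ten. The antibody was the same for all samples.

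The authors deposited 1 list of chromatin loops per group, with both replicates in 1 list and no columns for single replicates. Each list has 15 columns and no header: the 2 anchors of the loop, the PETs that join them, a flag for anchors on the same chromosome, their distance, the tags at each anchor, and significance values. The PETs of a loop were deposited as whole-number counts, not normalised. The deposited p-values and false discovery rates (FDR) were given both as such and as −log10 values, and every deposited FDR was below 0.05, with a highest value of 0.0499 in each list. No listed loop had fewer than 2 PETs. The loop caller, aligner and genome build are not given in the sources used here. The p-values of loops of 2 PETs with over 200 tags at each anchor equalled the Poisson probability of at least that many PETs when the product of the tags at both anchors, divided by 1 total per list, was taken as the number made by chance. That total was solved for each list and is called total tags below; its 5th to 95th percentiles over loops lay within 0.174% of the median in every list. A loop that is absent from a list fell below the authors' thresholds, so absence does not show that a contact was missing, and no limit on it is printed.

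Because each group had 1 pooled list, no difference between groups could be set against a spread between replicates. No test across samples was made and no p-value is given. Intervals are 95% intervals that cover counting error only: exact Poisson for numbers of loops, exact Clopper-Pearson for shares and for ratios of PETs, and binomial order statistics for medians. PETs are amplified molecules, so the true errors are wider.

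Coordinates are printed 1-based as the lists give them. Whether lists shared a coordinate system was tested by anchor overlap. Among the 4 lists of MH63 and ZS97, and between Dongjin and osemf2b, 50.4% to 96.4% of anchors of a list overlapped an anchor of the other, against 15.3% to 30.1% after moving them by 50 kb. Between these sets the overlap was 12.8% to 27.0% as given and 12.8% to 27.1% after moving. The MH63 and ZS97 lists were therefore compared with each other, Dongjin with osemf2b, and no position was compared between the sets. No annotation of either build was used here. The analyses planned on genes, including the lists of flowering, floral MADS-box and Polycomb genes, were replaced by the fallback fixed beforehand, which takes regions in place of genes. The locus targeted in osemf2b was not analysed here for the same reason.

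A loop counted as shared when both its anchors overlapped, by at least 1 bp, both anchors of a loop in the other list. Shares were set against 1000 circular shifts, in which all anchors of a chromosome were moved by the same random distance. Loops between chromosomes were also set against 1000 rewirings, in which partners were exchanged at random among the interchromosomal loops of the list. Exchanged pairs that fell on the same chromosome were left out, so anchors did not keep their exact numbers of loops. Shifts break the overlap of anchors as well as their pairing. A share above the shifts therefore does not show that the same anchors are paired. Loops within chromosomes and all loops together had no control that kept the anchors in place. For levels, overlapping anchors of all lists in 1 coordinate system were merged into regions (14152 for MH63 and ZS97, 10491 for Dongjin and osemf2b), and the PETs of all loops with an anchor in a region were summed and divided by the total PETs of the list. A region was compared when it had at least 20 PETs summed over both lists, and was called higher or lower when the ratio was at least 2-fold with a 95% interval that excluded 1. In these calls a region with no listed loop in a list entered the interval as 0 PETs and the ratio, also used for ranking, as a floor of 3 PETs, although PETs below the authors' thresholds may exist there. No fold is printed against such a region, and the calls were also counted over regions with a listed loop in both lists. Levels were not corrected for the tags at a region. The log2 ratios of PETs and of tags had a Pearson r of 0.84 in MH63 and 0.71 in ZS97 for root against seedling. For ZS97 against MH63 it was 0.58 in seedling and 0.71 in root, and for osemf2b against Dongjin 0.72. A difference in level is therefore not set apart from a difference in tags. Named regions are, per comparison, the 6 with the highest and the 6 with the lowest ratio, with 1 region per 50 kb, and per list the 3 anchors with the most partners. Other regions named in the text were chosen after their values were seen. The calls were checked on simulated data with 200 regions changed 4-fold or 8-fold per comparison. Between 81.5% and 92.0% of the changed regions were called across the comparisons, and 1.28% to 1.81% of unchanged regions were. The simulated PETs held counting error alone, with no threshold for listing a loop and no spread between libraries. These shares check the calculation and do not give the rate of false calls in the data.

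After thinning, p-values were computed again with the number made by chance reduced by the share of PETs kept. Dongjin anchors and loops found again in osemf2b were set against anchors moved by 50 kb and against Dongjin itself after its PETs had been thinned to those of osemf2b. Thinned Dongjin is a part of the same list and holds no spread between libraries. What it kept therefore does not show what a second Dongjin library would give. It held 36307 loops, whereas thinning with the common highest p-value left 23818.

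Alternatives fixed before the data were examined were minimum PETs of 5 or 10, thinning of PETs to 282020 in every list, shares of PETs, spans of at least 20 kb or weighted by PETs, anchor overlap of at least 50%, anchors widened by 5 kb, equal numbers of loops, an FDR of at most 0.005, other scalings of the levels, and intrachromosomal loops only. A common highest p-value of 0.0012, scaling on total tags, 10 kb bins, regions with a listed loop in both lists, thinning joined with a minimum of 5 PETs or with a common or stricter p-value, the controls for what was found again in osemf2b and the rewirings were chosen after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.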

Results

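H3K27me3-associated chromatin loops were mapped by ChIA-PET in 2 indica rice varieties, MH63 and ZS97, in seedlings and roots, and in seedlings of the japonica variety Dongjin and of osemf2b in the Dongjin background. H3K27me3 is the repressive histone mark set by Polycomb repressive complex 2, and OsEMF2b is a rice subunit of that complex. The 12 samples formed 6 groups of 2 replicates, and each group was represented by 1 list that pooled both. The lists held 695423 PETs in MH63 root, 509524 in MH63 seedling, 535937 in ZS97 root, 484060 in ZS97 seedling, 818847 in Dongjin and 282020 in osemf2b. Total tags, recovered from the p-values, were 41.3 M tags in MH63 root, 22.1 M in MH63 seedling, 13.4 M in ZS97 root, 51.2 M in ZS97 seedling, 39.4 M in Dongjin and 31.2 M in osemf2b. With 1 list per group there was no replicate error to set a difference against, and all intervals below are 95% intervals of counting error.

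Loop number, reach and hubs were compared first, as a description of H3K27me3-associated genome topology across varieties and tissues. The osemf2b list held 15913 loops (15667 to 16162), against 94432 in Dongjin (93831 to 95036). ZS97 root had the most loops, 110885 (110233 to 111540), and ZS97 seedling had 90390 (89802 to 90981). In MH63 the order of the tissues was the opposite, with 75056 loops in root (74520 to 75595) and 86383 in seedling (85808 to 86961). Loops between chromosomes made up 71.8% of the list in ZS97 seedling (71.5 to 72.1) and 62.3% in ZS97 root (62.0 to 62.6). The share was 55.7% in MH63 seedling, 49.1% in MH63 root, 47.6% in Dongjin and 57.2% in osemf2b. Most of these interchromosomal loops were weak. The share of them that rested on 2 PETs was the lowest of the 6 lists in osemf2b, at 53.3%, and the highest in ZS97 root, at 73.5%. For loops within a chromosome that share was lowest in MH63 root, at 19.8%, and highest in ZS97 root, at 37.8%. Interchromosomal loops held 15.7% of the PETs in MH63 root and 42.1% in ZS97 seedling. In osemf2b, 107 interchromosomal pairs of regions had at least 100 PETs.

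Loops within a chromosome had a median span of 212 kb in Dongjin (208 to 216) and 104 kb in osemf2b (98.7 to 109). The median was 181 kb in MH63 seedling and 103 kb in MH63 root, and 143 kb in ZS97 seedling and 154 kb in ZS97 root. Loops over 1 Mb made up 24.6% of intrachromosomal loops in MH63 seedling but 12.9% in MH63 root, while in ZS97 they made up 28.7% in seedling and 24.4% in root. Weighted by PETs, the median span was alike in MH63 seedling and root, at 67.7 and 67.9 kb, and was longer in osemf2b (137 kb) than in Dongjin (79.5 kb). Among loops of at least 5 PETs, MH63 had more in root (25359) than in seedling (18153), and ZS97 had 18155 in root and 18248 in seedling. Thinned to the PETs of osemf2b, Dongjin still had 36365 loops, and 10562 of at least 5 PETs against 5359 in osemf2b. With a common highest p-value as well, Dongjin had 23818 loops and osemf2b 15814.

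**Figure D1:**
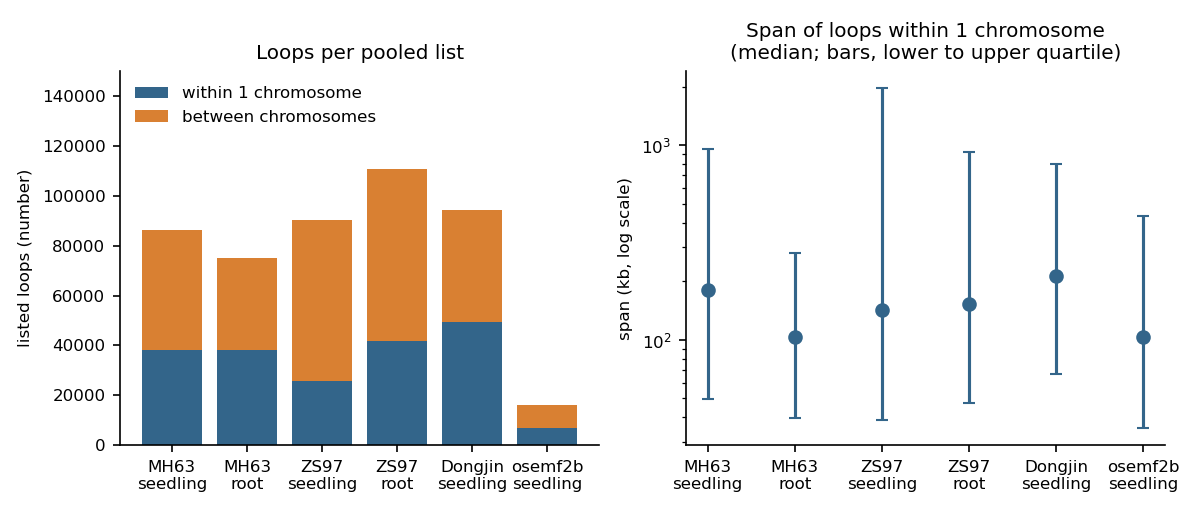
Left, number of listed loops in each of the 6 pooled lists, stacked by loops within 1 chromosome and between chromosomes. Right, span of intrachromosomal loops in kb on a log axis, with points at the median and bars from the lower to the upper quartile. The osemf2b list is the smallest, with 15913 loops against 94432 in Dongjin.

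The best-connected anchors were wide domains, 75.6 to 178 kb across. In MH63 seedling, the anchor at 17589452 to 17727760 on chromosome 12 had 293 partners, 101 of them on other chromosomes, and 7414 PETs. Another MH63 seedling hub was 17000982 to 17178879 on chromosome 2, with 214 partners. The domain on chromosome 12 led in MH63 root as well, at 17578538 to 17728023 with 109 partners. A domain near 26.1 Mb on chromosome 11 was among the 3 leading hubs of MH63 seedling (26114830 to 26190430, 228 partners), MH63 root (26110617 to 26204868, 81 partners) and ZS97 root (26116809 to 26201911, 145 partners). ZS97 root was led by 18762889 to 18842540 on chromosome 12, with 167 partners, which overlaps the MH63 root hub at 18742330 to 18842915 with 96. The hubs of ZS97 seedling lay elsewhere, at 1769107 to 1865129 on chromosome 7 with 170 partners, 6152283 to 6250508 on chromosome 5 with 155, and 2357574 to 2463662 on chromosome 10 with 150. In that list most partners of these hubs were on other chromosomes: 105, 113 and 104. In Dongjin and in osemf2b the same domain on chromosome 12 came first. It had 232 partners in Dongjin, at 19287756 to 19424123, and 99 in osemf2b, at 19276316 to 19426772, where it carried 17716 PETs against 7170. The tags at this anchor numbered 365106 in osemf2b and 109751 in Dongjin, so more PETs are not set apart from more tags there. The other hubs were 25803300 to 25900199 and 18530786 to 18627588 on chromosome 11 in Dongjin, with 195 and 194 partners. In osemf2b they were 5537972 to 5674372 on chromosome 1 with 82 and 1860936 to 1969128 on chromosome 7 with 75.

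Roots were set against seedlings in MH63 to ask how H3K27me3 contacts differ between tissues. Of 9468 regions compared, 3803 had at least 2-fold more PETs in root, scaled on the total of each list, and 1569 at least 2-fold fewer. The region higher in root by the widest margin, at 19456834 to 19485252 on chromosome 12, had 1449 PETs in root and no listed loop in seedling. Regions on chromosome 11 at 16593408 to 16632784 and 25397793 to 25413036 had 1035 and 825 PETs in root, and those at 14761677 to 14789198 on chromosome 10 and 18609133 to 18624038 on chromosome 12 had 889 and 792, all without a listed seedling loop. At 15762335 to 15785545 on chromosome 4 there were 500 PETs in root and 2 in seedling, a 183-fold ratio (50.4 to 1517). In the other direction, 26890234 to 26917663 on chromosome 4 had 1229 PETs in seedling and no listed loop in root. The same held for 23121091 to 23134730 on chromosome 12 with 576 seedling PETs, 26113140 to 26120325 and 22675411 to 22687832 on chromosome 6 with 403 and 243, 25414663 to 25425505 on chromosome 3 with 294, and 21858955 to 21866379 on chromosome 2 with 259.

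Of the MH63 root loops, 16.3% (16.0 to 16.5) were found again in seedling, 7.90 times the mean of the shifts (2.06%), and none of 1000 shifts reached it. Shared anchor positions alone can raise a share above the shifts: 75.4% of MH63 root anchors overlapped a seedling anchor, against 25.5% moved by 50 kb. Sharing differed by kind of loop. Within a chromosome 31.6% of root loops were shared (31.1 to 32.1), against 4.03% after shifting. Between chromosomes 0.393% were shared (0.332 to 0.462), against 0.0195% after shifting and 0.181% after exchanging partners, and none of 1000 rewirings reached the observed share. Over regions with a listed loop in both tissues, 2183 were higher and 1293 lower. Tags went with PETs there: of 7571 regions with both, 3115 had at least 2-fold more tags in root, scaled on total tags. At least 2-fold fewer tags were found in 487. The excess of higher regions depended on the scaling: the median log2 ratio was 0.55 when scaled on total PETs, 1.00 without scaling (4655 higher, 991 lower) and 0.08 when scaled on shared loops (3118 higher, 2371 lower).

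In ZS97, 2430 of 9011 regions were at least 2-fold higher in root and 2402 at least 2-fold lower. The 2 regions that led in MH63 root led here too: 19456834 to 19485252 on chromosome 12 had 1071 PETs in root and 16593408 to 16632784 on chromosome 11 had 768, with no listed loop in ZS97 seedling. The region at 18609133 to 18624038 on chromosome 12 had 675 root PETs and none listed in seedling in ZS97, as in MH63. Chromosome 11 at 7548459 to 7583670 had 573 PETs in ZS97 root and none listed in seedling, beside 475 and 2 in MH63. At 19724087 to 19760349 on chromosome 12, ZS97 had 758 PETs in root and none listed in seedling, and MH63 had 1810 and 222. The region at 1899369 to 1923420 on chromosome 4 set the varieties apart, with 723 PETs in ZS97 root and none listed in ZS97 seedling but 732 and 668 in MH63. Lower in ZS97 root were 26157769 to 26161689 on chromosome 6, with 427 seedling PETs, and 23121091 to 23134730 on chromosome 12, with 413. Chromosome 2 at 21858955 to 21866379 had 312 seedling PETs, and chromosome 1 at 6810803 to 6815460 had 171. Each of these 4 regions also had fewer PETs in root than in seedling in MH63. The remaining pair, 4511769 to 4522415 on chromosome 2 with 265 PETs and 19026471 to 19029125 on chromosome 11 with 215, was listed in ZS97 seedling alone among the 4 lists.

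The tissue contrast went the same way in both varieties. Across 7544 regions compared in both, the log2 root over seedling ratios had a Pearson r of 0.74 and a Spearman rho of 0.69; regions are not independent replicates. In both varieties 1583 regions were higher in root, where independent calls would give 645, and 785 were lower, against 318. Opposite calls were made for 150 regions, against 926. Scaled on total tags, 1897 regions were higher in root in both varieties, 246 lower in both and 1207 opposite, where independent calls would give 1547, 84.6 and 1752. Over the 5940 regions with a listed loop in all 4 lists, r was 0.54, with 500 higher in both, 548 lower in both and 126 opposite. The share of compared regions higher in root in both varieties was 32.4% on chromosome 11 (204 of 630) and 28.3% on chromosome 12 (139 of 491), and lowest on chromosome 1, at 14.5% (140 of 965). Regions higher in root in both varieties had a median width of 4.88 kb and those lower in both 2.80 kb, beside 4.57 kb for all regions compared in both. Regions were merged from the anchors of these same lists, and root anchors were wider. Median anchor widths were 2505 bp in MH63 root and 2368 bp in ZS97 root, against 1677.5 and 1674 bp in their seedlings. The difference in region width may therefore be built in.

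Of the ZS97 root loops, 9.16% (8.99 to 9.33) were found in ZS97 seedling, 10.3 times the mean of the shifts, with 22.7% within chromosomes (22.3 to 23.1) and 0.956% between them (0.885 to 1.03). None of 1000 shifts reached these shares, and exchanging partners gave 0.333% between chromosomes. The balance of regions depended on the scaling, since ZS97 root had the fewest total tags: scaled on total tags, 6660 regions were higher in root and 595 lower, with a median log2 ratio of 1.94 in place of -0.15. All 12 named regions kept their direction under that scaling, but this was built in and tests nothing. The scaling moved every log2 ratio by the same 2.085, and these regions had been chosen for ratios far more extreme. Counted on loops within chromosomes alone, 2330 regions were higher and 1012 lower. Over regions with a listed loop in both tissues, 782 were higher and 1832 lower.

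**Figure D2:**
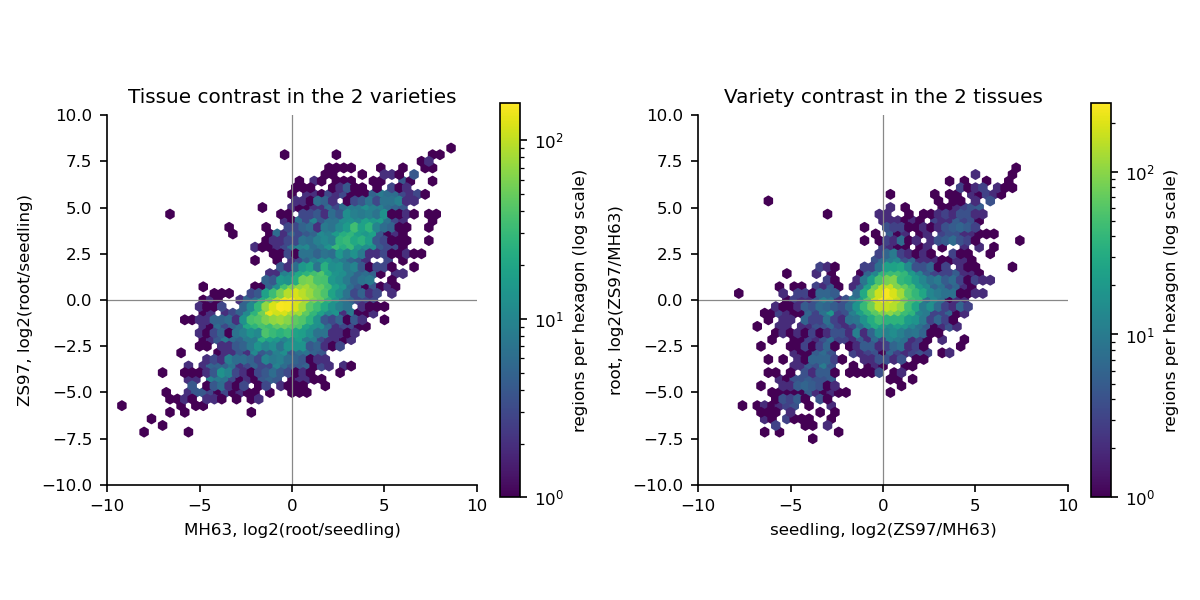
Log2 ratios of PETs, scaled on the total PETs of each list, for merged regions, with the number of regions per hexagon on a log colour scale and regions without a listed loop in 1 list set at 3 PETs. Left, root over seedling in MH63 against ZS97 (7544 regions, r of 0.74); right, ZS97 over MH63 in seedling against root (6598 regions, r of 0.57).

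The varieties were compared in seedlings next. Their lists share 1 coordinate system, so a difference in sequence between the varieties cannot be told apart from a difference in contacts at a region. In ZS97, 2307 of 7935 regions were at least 2-fold higher than in MH63 and 847 at least 2-fold lower. The 6 regions highest in ZS97 were 0.710 to 7.52 kb wide, and none had a listed loop in MH63 seedling. They were 12178637 to 12186151 on chromosome 4 with 462 PETs, 18470307 to 18475081 on chromosome 8 with 460, 21238916 to 21242836 on chromosome 3 with 367, 18767311 to 18768020 on chromosome 11 with 358, and, on chromosome 5, 7246227 to 7250293 with 320 and 27955168 to 27958380 with 281. Of the 462 PETs at the chromosome 4 region, 348 led to 16855769 to 16867939 on chromosome 8. Of the 367 PETs at the chromosome 3 region, 317 led to 4784808 to 4847409 on chromosome 8. Neither region had a listed partner within 1 Mb in ZS97 seedling. MH63 seedling was higher at 1899369 to 1923420 on chromosome 4 with 668 PETs, 26188781 to 26197740 on chromosome 6 with 550, 29589606 to 29606657 and 25511766 to 25532546 on chromosome 11 with 328 and 326, and 7070016 to 7079557 and 15693956 to 15715448 on chromosome 12 with 327 and 302, none with a listed loop in ZS97 seedling.

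Within chromosomes 44.7% of the ZS97 seedling loops (44.1 to 45.3) were found in MH63 seedling, against 2.84% after shifting, and between chromosomes 0.316% (0.274 to 0.362), against 0.0151% after shifting and 0.238% after exchanging partners. No shift or rewiring reached the observed values. Over all loops the share was 12.8% (12.6 to 13.1). The excess of regions higher in ZS97 was absent within chromosomes, with 847 higher and 974 lower, and turned round when scaled on total tags, with 726 higher and 3458 lower, with a median log2 ratio of -0.86 in place of 0.43. Over regions with a listed loop in both varieties 1908 were higher and 290 lower.

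In roots, 1573 of 9785 regions were at least 2-fold higher in ZS97 and 2130 at least 2-fold lower. Regions high in ZS97 with no listed loop in MH63 root were 1121617 to 1132094 on chromosome 4 with 371 PETs, 18470307 to 18475081 on chromosome 8 with 340, 24426324 to 24432394 and 19003885 to 19009182 on chromosome 11 with 290 and 279, 21238916 to 21242836 on chromosome 3 with 242, and 20251488 to 20260905 on chromosome 2 with 228. The regions on chromosomes 8 and 3 were also among the 6 highest in seedling. MH63 root was higher at 13491449 to 13514863 and 13668210 to 13679056 on chromosome 12, with 742 and 573 PETs, at 9329529 to 9351930 on chromosome 9 with 578, at 29316393 to 29334801 and 26209040 to 26217884 on chromosome 11 with 550 and 459, and at 16736705 to 16744534 on chromosome 10 with 471. None of these had a listed loop in ZS97 root.

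Of the ZS97 root loops, 17.7% (17.5 to 17.9) were found in MH63 root, with 46.5% within chromosomes (46.0 to 46.9) against 5.25% after shifting. Between chromosomes 0.289% were shared (0.251 to 0.332), against 0.0179% after shifting and 0.109% after exchanging partners, and no shift or rewiring reached the observed values. Across 6598 regions compared in both tissues, the ZS97 over MH63 log2 ratios had a Pearson r of 0.57 and a Spearman rho of 0.32 between seedling and root. In both tissues 448 regions were higher in ZS97, where independent calls would give 231, and 401 were lower, against 102; 155 went opposite ways, against 325. Scaled on total tags, 1854 went opposite ways, against 2060 by independent calls. Over the 5791 regions with a listed loop in all 4 lists, r was 0.20, with 240 higher in both, 99 lower in both and 131 opposite. The regions with at least 20 PETs in both tissues of a variety and no listed loop in either tissue of the other numbered 194 of 4752 in MH63 (4.08%, 3.54 to 4.68) and 143 of 4891 in ZS97 (2.92%, 2.47 to 3.44). Whether the sequence of these regions is present and mappable in the other variety was not tested. Over regions with a listed loop in both varieties, 964 were higher in ZS97 root and 1129 lower. In root the direction of the balance turned with the scaling, to 2534 higher and 1634 lower when scaled on shared loops and 5528 higher and 1190 lower on total tags, while without scaling it was 1113 and 2919; the median log2 ratios were 0.38, 1.20 and -0.43, against -0.05 in the main comparison.

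**Figure D3:**
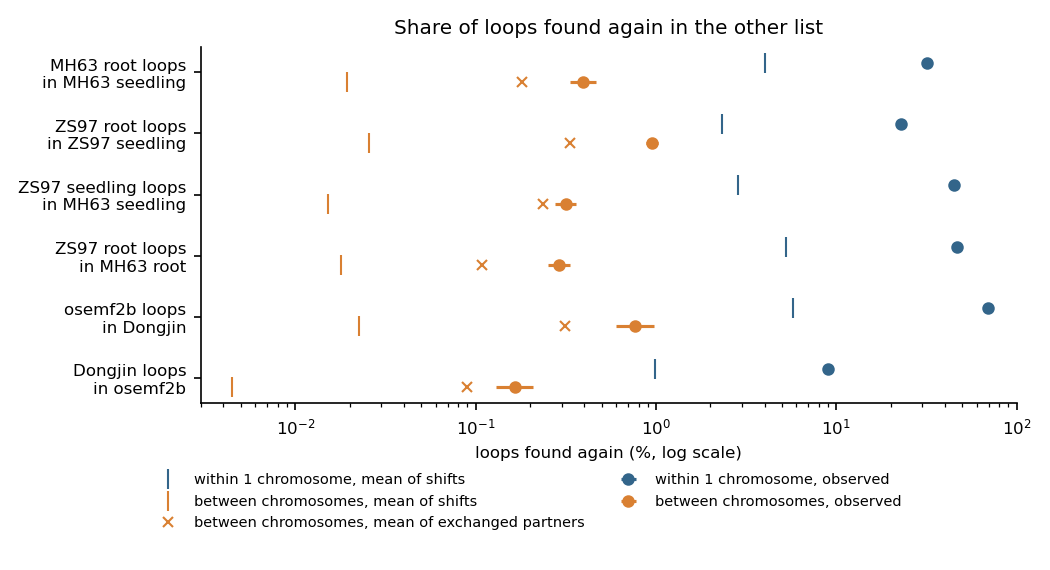
Percentage of the loops of 1 list found again in another, on a log axis, for loops within a chromosome and between chromosomes. Points are observed shares with exact 95% intervals, ticks the mean of 1000 shifts and crosses the mean of 1000 rewirings. Observed interchromosomal shares lie between 0.165% and 0.956%, and intrachromosomal shares between 9.02% and 69.5%.

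The osemf2b seedlings were set against Dongjin to ask how H3K27me3 contacts change with this Polycomb subunit. Levels were lower in most regions: of 8032 regions compared, 5946 had at least 2-fold fewer scaled PETs in osemf2b and 417 at least 2-fold more. In osemf2b 3225 regions had no listed loop at all, and in Dongjin 26. Over regions with a listed loop in both, 2721 were lower in osemf2b and 391 higher, with a median log2 ratio of -1.48. Tags fell as well: of these 4781 regions, 3193 had at least 2-fold fewer tags, scaled on total tags, and 671 at least 2-fold more. Fewer contacts therefore cannot be told apart from fewer tags at the regions. The named regions lost from the list were 18421420 to 18427124, with 990 Dongjin PETs, and 23039695 to 23056692, with 873, on chromosome 11. Chromosome 6 at 21004092 to 21021953 had 880, chromosome 2 at 7368270 to 7382503 had 855 and chromosome 7 at 2153205 to 2156857 had 756. At 17479533 to 17488596 on chromosome 11 there were 510 PETs in Dongjin and 2 in osemf2b, a ratio of 0.0114 (0.00138 to 0.0413). The regions highest in osemf2b were 1.56 to 5.76 kb wide and had no listed Dongjin loop: 5967393 to 5973156 on chromosome 4 with 212 PETs, 6637906 to 6640464 and 15011919 to 15013695 on chromosome 5 with 92 and 52, 5558804 to 5560603 on chromosome 9 with 92, 2747793 to 2749516 on chromosome 7 with 80, and 12472538 to 12474096 on chromosome 12 with 57.

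Nearly all osemf2b anchors, 96.4% (95.9 to 96.8), overlapped a Dongjin anchor, but 50.4% of Dongjin anchors (49.4 to 51.3) overlapped one in osemf2b. In Dongjin thinned to the PETs of osemf2b, 88.4% of Dongjin anchors overlapped one. Thinned Dongjin was drawn from the Dongjin list itself, so high values there are built in and do not stand for a second Dongjin library. With Dongjin anchors in 4 equal classes by width, the share found again was 17.7% (16.3 to 19.3) in the narrowest class and 88.0% (86.7 to 89.2) in the widest. Moved by 50 kb these classes gave 8.31% and 30.4%, and in thinned Dongjin 69.1% and 99.96%, so both controls rose with width as well. By tags per bp, the class with the most reached 86.8% (85.5 to 88.1), against 27.1% moved and 99.5% in thinned Dongjin. Of intrachromosomal Dongjin loops under 100 kb, 14.3% were found again (13.8 to 14.9), and of those over 1 Mb 1.44% (1.22 to 1.67), where thinned Dongjin kept 63.2% and 36.7%. Among loops of at least 10 PETs these shares were 30.98% and 9.04%, where thinned Dongjin kept 98.45% and 98.1%. Loops of 100 PETs or more were found again in 76.0% (73.2 to 78.6), and thinned Dongjin kept 100%. The PETs that were left were concentrated, with 41.9% of anchor PETs at the top 1% of anchors in osemf2b against 21.1% in Dongjin.

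Of the osemf2b loops, 30.2% (29.5 to 30.9) were found in Dongjin, 12.1 times the mean of the shifts. Of the Dongjin loops, 4.81% (4.67 to 4.95) were found in osemf2b, 9.29 times. Both shares moved with the setting: with equal numbers of loops they were 26.4% and 23.1%, and among loops of at least 5 PETs 56.1% and 10.5%. Within chromosomes these shares were 69.5% and 9.02%, and between chromosomes 0.769% (0.600 to 0.970) and 0.165% (0.129 to 0.207). Exchanging partners gave 0.312% and 0.0894% between chromosomes, and no shift or rewiring reached the observed shares. The osemf2b list also held 107 interchromosomal pairs of regions with at least 100 PETs, with 37.9% of its interchromosomal PETs, where the other lists held between 1 and 13 such pairs. The strongest joined 2691766 to 2744912 on chromosome 10 with 19276316 to 19426772 on chromosome 12 by 1586 PETs, and 103 of the 107 had no listed Dongjin loop. In those 103 the PETs were a median of 1.31 times the number that the tags at both anchors give by chance. Levels in osemf2b were lower under every scaling tried, with a median log2 ratio of -1.92 on total PETs and -2.07 on shared loops. It was -3.12 on total tags (97 higher, 7134 lower) and -3.46 without scaling (62 higher, 7349 lower). A scaling moves all log2 ratios by the same amount. As osemf2b had fewer PETs, also per total tag, scaling on total tags or not at all could only deepen the loss. These 2 settings therefore do not test it.

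**Figure D4:**
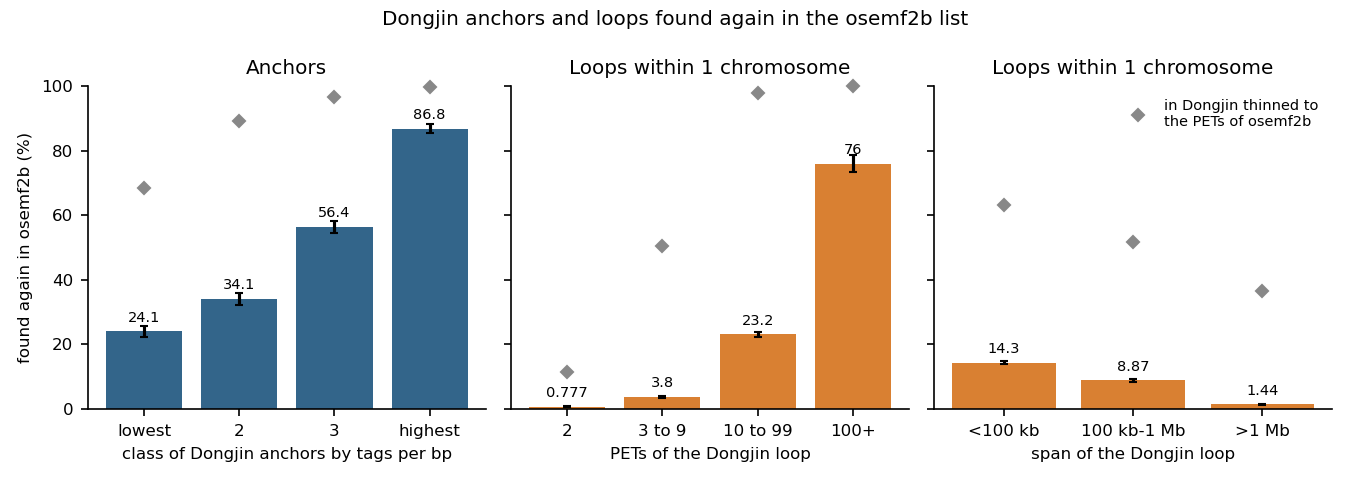
Percentage of Dongjin anchors, and of Dongjin loops within a chromosome, found again in the osemf2b list, with exact 95% intervals as error bars. Anchors are split into 4 equal classes by tags per bp, and loops by PETs and by span. Diamonds give the share kept in Dongjin thinned to the PETs of osemf2b. The share rises from 24.1% to 86.8% with tags per bp and from 0.778% to 76.0% with PETs, and falls from 14.3% to 1.44% with span.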

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

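The minimum of 5 or 10 PETs and the thinning were settings fixed beforehand; the common and stricter p-values, the settings that join thinning with another, and the use of all of these as tests of an explanation were chosen after the results had been seen. Each value below comes from 1 list per group, so the differences between varieties were not tested.

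The number of loops changed in opposite directions between tissues in the 2 varieties: the root over seedling ratio was 0.869 in MH63 (0.860 to 0.877) and 1.23 in ZS97 (1.22 to 1.24). Among loops of at least 5 PETs it was 1.40 and 0.995, and with PETs thinned to equal numbers as well 1.19 and 0.924. Among loops of at least 10 PETs it was 1.655 in MH63 (1.609 to 1.703) and 1.062 in ZS97 (1.028 to 1.097). Loops of few PETs may therefore account for the deficit in MH63 root. In ZS97 root the excess was absent at 5 PETs but present in small part at 10, so they may account for part of it. The parts of unequal numbers of PETs and of different highest p-values cannot be told apart: with a common p-value of 0.0012 the ratio was 1.24 and 0.982, with thinning alone 0.794 and 1.01, and at equal PETs with 1 highest p-value from 0.0012 down to 7.143e-06 from 0.876 to 1.04 in MH63 and from 0.989 to 1.81 in ZS97. Thinning alone could only lower the ratio in MH63, whose root list has more PETs, so it decides nothing there. A difference between the varieties in how tissues form loops remains open and untested, with its direction set by the cutoff.

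The median span of intrachromosomal loops also moved in opposite directions, with a root over seedling ratio of 0.573 in MH63 and 1.08 in ZS97. In MH63 the median in root and in seedling was 84.5 and 98.0 kb at 5 PETs and 128 and 242 kb with spans of at least 20 kb, but 71.3 and 70.7 kb at 10 PETs and 67.9 and 67.7 kb weighted by PETs. In ZS97 the longer median in root held in the main setting alone: the median was shorter in root than in seedling at 5 PETs (69.0 and 76.0 kb), at 10 PETs (48.3 and 58.7 kb), with spans of at least 20 kb (203 and 210 kb) and weighted by PETs (56.7 and 58.5 kb). Among regions, 150 were called higher in root of one variety and lower in root of the other, 132 of them higher in MH63 root and 18 higher in ZS97 root.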

How the results depend on the processing

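No paired analysis was possible because each list pools both replicates of its group. The planned analyses of gene lists and the settings on gene bodies were not run, since no annotation of the builds was used here. The common highest p-value, scaling on total tags, 10 kb bins, regions with a listed loop in both lists, thinning joined with another setting and the alternatives for the share of Dongjin loops in osemf2b were chosen after seeing the data. Values are in the order seedling then root of MH63, seedling then root of ZS97, Dongjin, osemf2b. Loops with no replicates have intervals of counting error alone, so even small moves exceed them. Of the alternatives, 122 moved a value beyond its interval, or a count by over 1.5 times, and 52 did not. The cause was not tested where no value is given for it. The osemf2b list had the fewest loops under each setting, while the order of root and seedling depended on the setting in both varieties.

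Loops of at least 5 PETs numbered 18153, 25359, 18248, 18155, 28335 and 5359, and of at least 10 PETs 7667, 12689, 7203, 7648, 13562 and 3002. Thinned to equal PETs there were 45288, 35973, 50691, 51129 and 36365, with osemf2b as it was. With a common highest p there were 49528 in MH63 seedling, 61614 in MH63 root, 59157 in ZS97 seedling, 58062 in ZS97 root and 60801 in Dongjin. Thinned and of at least 5 PETs they numbered 9673, 11483, 9855, 9106, 10562 and 5359, and thinned with a common highest p 29173, 25545, 33049, 32673 and 23818, with osemf2b near its main value at 15814. Fewer loops follow from the construction of these settings. The interchromosomal share was 19.4%, 15.2%, 40.5%, 18.1%, 16.6% and 32.0% among loops of at least 5 PETs, and 7.28%, 5.01%, 22.6%, 5.45%, 6.61% and 24.7% at 10 PETs. After thinning it was 45.3%, 31.02%, 64.6%, 50.5% and 29.0%, and as a share of PETs 25.4%, 15.7%, 42.1%, 32.6%, 16.4% and 25.0%. ZS97 seedling had the highest share under each of these except at 10 PETs, where osemf2b did.

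Median spans were 98.0, 84.5, 76.0, 69.0, 142 and 85.5 kb at 5 PETs, and 70.7, 71.3, 58.7, 48.3, 102 and 84.3 kb at 10 PETs. With spans of at least 20 kb they were 242, 128, 210, 203, 252 and 147 kb, and weighted by PETs 67.7, 67.9, 58.5, 56.7, 79.5 and 137 kb.

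For shared loops the order is MH63 root in seedling, ZS97 root in seedling, ZS97 in MH63 seedling, ZS97 in MH63 root, osemf2b in Dongjin and Dongjin in osemf2b. An overlap of 50% left each share within its interval. Widening anchors by 5 kb gave 25.2%, 15.1%, 16.8%, 22.7%, 33.5% and 8.46%. Loops of at least 5 PETs gave 25.9%, 29.4%, 36.7%, 57.5%, 56.1% and 10.5%, and an FDR of at most 0.005 gave 31.7%, 14.2%, 38.8%, 32.0%, 58.5% and 8.65%. With equal numbers of loops, MH63 root in seedling stayed within its interval and the others were 10.9%, 13.3%, 24.8%, 26.4% and 23.1%.

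For regions higher or lower, scaling on shared loops gave 2371 lower in MH63 root and 2534 higher in ZS97 root over MH63 root. Without scaling there were 991 lower in MH63 root and 62 higher in osemf2b. Within chromosomes alone there were 1012 lower in ZS97 root than in seedling and 847 higher in ZS97 than MH63 seedling. Scaled on total tags, ZS97 root over seedling had 6660 higher and 595 lower, ZS97 over MH63 seedling 726 and 3458, ZS97 over MH63 root 5528 and 1190, and osemf2b 97 higher. With 10 kb bins osemf2b had 759 higher. Over regions with a listed loop in both lists there were 2183 higher in MH63 root and 782 higher in ZS97 root than in seedling, 290 lower in ZS97 than MH63 seedling, 964 higher and 1129 lower in ZS97 than MH63 root, and 2721 lower in osemf2b; these settings test fewer regions. Under total tags, 1897 regions were higher in root in both varieties and 246 lower, with 1207 opposite, in place of 1583, 785 and 150. Under that scaling all named regions kept their direction. This was built in and tests nothing, as they had been chosen for ratios far beyond the shift.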

Other observations

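The tests of explanations in this part were all chosen after the results they bear on had been seen.

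Pairs of regions on different chromosomes seldom recurred among the 4 lists of MH63 and ZS97: 99.2% of 216737 pairs were in 1 list and 20 pairs were in all 4. On the same chromosome 71.7% of 84500 pairs were in 1 list and 5554 were in all 4. Among the 20 interchromosomal pairs in all 4 lists, the one with the most PETs joined 21496647 to 21509825 on chromosome 11 with 23054180 to 23102526 on chromosome 6. It had 125 PETs in MH63 seedling, 107 in MH63 root, 76 in ZS97 seedling and 120 in ZS97 root. The next of these 20 joined 9935249 to 9937479 on chromosome 5 with 18636041 to 18671231 on chromosome 8, by 60, 76, 62 and 17 PETs in the same order.

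Some recurrent pairs lay between the starts of chromosomes 11 and 12, which hold a duplicated segment in rice. Whether reads of 1 copy had been placed on the other was not tested, so these pairs need not be contacts. The region at 808661 to 854704 on chromosome 12 paired with 791087 to 816628 on chromosome 11 by 9 and 93 PETs in MH63 seedling and root and by 3 and 77 in ZS97 seedling and root. Pairs with both regions in the first 3 Mb of these chromosomes made up 3 of the 66 pairs found in 3 or 4 lists (4.55%, 0.947 to 12.7) and 53 of 215013 pairs found in 1 list (0.0246%, 0.0185 to 0.0322). Their median difference in position was 85.6 kb in the first set and 740 kb in the second.

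Interchromosomal pairs of at least 20 PETs in both tissues of ZS97 and in neither MH63 list numbered 23 of the 35 that reached 20 PETs in both ZS97 tissues; for MH63 the numbers were 2 of 5. Random ligation between heavily tagged anchors is argued against: the PETs in ZS97 seedling were a median of 147 times the number that the tags give by chance. A candidate explanation is sequence that lies elsewhere in ZS97 than in the coordinates used. With the PETs of the pair itself left out, the region of the pair with fewer PETs had a median of 7.73% of its other PETs within 1 Mb on its own chromosome, against 28.6% in all other regions with their strongest interchromosomal pair left out and 55.9% in those of them whose pair had at least 20 PETs. More of these PETs lay near the partner than near itself in 6 of the 20 regions with at least 10 of them, against 104 of 7479 and 9 of 433, although the median share near the partner was 0%. The regions of the 12 pairs also found in MH63 gave 5.52%, and 5 of the 11 with at least 10 such PETs had more near the partner. On both measures the regions of the ZS97 pairs differed from other regions, but not clearly from those of the pairs also found in MH63. Displaced sequence and true contacts that differ between the varieties cannot be told apart from these few pairs.

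The 103 interchromosomal pairs of at least 100 PETs in osemf2b without a Dongjin loop may reflect random ligation between anchors with many tags. Their PETs were a median of 1.31 times the number given by chance, with a range of 1.09 to 1.75, whereas the 3 pairs of 100 PETs or more in Dongjin had a median of 27.9; among pairs of 10 to 99 PETs the medians were alike, 2.42 in osemf2b and 2.785 in Dongjin. The tags at the anchors gave a median of 129 PETs by chance per pair in osemf2b and 15.03 in Dongjin. A smaller Dongjin library is excluded, as its total tags were 1.26 times those of osemf2b. How the tags of osemf2b came to be concentrated in these 132 regions was not tested, and a redistribution of H3K27me3 in osemf2b stays open.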
